A study of Homo sapiens with 21 samples.

How the data were processed

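Messenger RNA was profiled in 21 libraries from 2 human breast cancer cell lines, in 7 groups of 3, each numbered as biological repeat 1 to 3. MCF7 and MDA-MB-231 parental cells and PKM2 knockout cells of each line gave 12 libraries. MDA-MB-231 cells with a control vector and 2 lentiviral clones that overexpress TMEM33 (clone 1 and clone 8) gave 9. Per the labels' protocols, total RNA was taken with a column kit and libraries were made with the TruSeq RNA version 2 kit, which does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, STAR 2.5.2b and genome build hg38 were used. The counting program, the annotation release and any filter are not given in the sources used here.

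The authors deposited an FPKM table (fragments or reads per kilobase of gene, scaled by library size) of 59921 genes for the 12 knockout-design libraries, rounded to 2 decimals. The authors also deposited tables of 793 genes for MCF7 and 473 for MDA-MB-231 that hold a size-factor scaled signal (normalized counts) and, per the file headers, the authors' log2 fold changes; each listed gene has an absolute log2 fold change of at least 1, so these shorter tables served only for relative depth and for a comparison of calls. For the clones, the authors deposited 2 tables of 57726 genes with normalized counts (a coverage signal divided by a size factor per library), their own log2 fold changes and, per the file headers, adjusted p-values, whose method is not given. The vector columns of both clone tables differed by at most 4.83e-05, so the 9 libraries share a scaling. Dividing each library by the value of 1 read, estimated from its lowest values, gave whole reads within 0.01 for 100% of the values above 0. Gene symbols that had been turned into dates (28 in the FPKM table) were restored from the gene identifiers. That table holds 0 genes of the mitochondrial genome and the clone tables hold 37.

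Recovered totals of the clone-design libraries are given with the results. The FPKM table gives no depth. Relative depth from the shorter tables ranged from 0.836 to 1.29 times that of parental replicate 1 in MCF7 (114 genes) and from 0.696 to 1.52 in MDA-MB-231 (98 genes), and no counting interval was given for FPKM values.

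Knockout and parental libraries of both lines were fitted together with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with a mean per group, an intensity trend in the variance and 8 residual degrees of freedom. Genes with a mean of at least 1 FPKM in the line were tested. The difference of the knockout effects, MDA-MB-231 minus MCF7, was a contrast in the same fit, for genes with a mean of at least 1 FPKM in at least 1 line. Each clone was compared with the vector libraries, and clone 8 with clone 1, by limma-trend on log2(normalized count + 1) for genes with a mean of at least 10, with 3 libraries against 3. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The design had assumed raw counts for the clones where these could be had; normalized counts were deposited, so limma was used and edgeR 4.0.16 (quasi-likelihood test) on the recovered reads served as an alternative. A count model for the knockout libraries was not run, since the table of all genes is in FPKM and the tables with normalized counts list only genes with an absolute log2 change of at least 1.

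31 gene lists were written before the data were examined, as were the comparisons, tests and the alternatives not named below as added. Lists with at least 5 tested members were tested with camera (limma) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list. The list counts in the text use the adjustment over all genes tested and, beside it, the adjustment over the list alone. Genes named were chosen by a rule fixed before the data were examined. It takes PKM, TMEM33, SCAP, SREBF1, SREBF2, INSIG1, RNF5, LDLR, HMGCR, HMGCS1, SQLE, FASN, SCD and ACACA in each comparison. It adds the 8 largest called rises and falls per comparison among genes with ordinary names, no overlap between the groups' libraries and a mean of at least 5 FPKM or 100 normalized counts in the higher group. It adds up to 4 called members with the largest change per list, up to 6 genes per overlap and direction, and 5 at each end of a tested difference. Genes of chromosome arm 4p outside this rule were chosen after their values were seen.

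Values are means with the standard deviation (SD) over n = 3 libraries, and changes are log2 differences with limma's standard error (SE). Where a group had 0 reads of a gene, the fold is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads, the ratio of group means is given with a 95% interval (exact binomial, conditional on the total reads). Both cover counting error only. Permutation tests of single genes were exact and two-sided; with 3 libraries against 3 they cannot give a p below 0.1. P-values measure the spread between these libraries and not between independently made knockouts or clones. Gene identifiers were matched without their version to a Gencode release 44 annotation of hg38: 93.5% of the FPKM table's and 98.8% of the clone tables' identifiers matched, and coordinates come from it. GC content and exonic length were available for 100% of the protein-coding genes used in the GC comparisons.

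Alternatives were other pseudocounts (0.1 and 1 for FPKM, 0.5 and 5 for counts), no filter on low values, a minimum mean of 5 FPKM or 50 normalized counts, median-centring, quantile normalization, the replicate number as a block, no intensity trend, robust variance, a fit of the cell line alone, all 9 clone-design libraries in 1 fit, an estimated correlation for lists and leaving out each library in turn. A correction of each library for a smooth trend on GC content and exonic length, and camera with a variance trend, were added after the data had been seen. The fitting code was tested on simulated data with known changes. For MCF7, where 14302 genes were tested, limma recovered 39.4% of genes changed by 0.5 and 82% of those changed by 1 on the log2 scale, with 2 false calls among 123. For clone 1, where 17910 genes were tested, it recovered 46% and 81.8%, with 6 false calls among 133; edgeR on 18176 genes recovered 63% and 99%, with 3 false calls among 165. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 served for reading the tables and for drawing.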

Results

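The data are RNA sequencing profiles of MCF7, an oestrogen receptor positive luminal breast cancer line, and MDA-MB-231, a triple-negative mesenchymal-like line. Both lines were profiled as parental cells and after knockout of PKM2, a splice form of the glycolytic enzyme gene PKM. MDA-MB-231 cells were also profiled with a control vector and as 2 clones overexpressing TMEM33, a protein of the endoplasmic reticulum membrane. Each of the 7 groups had 3 libraries. The series title places the question in lipid homeostasis and the stability of SCAP, the escort protein of the SREBP transcription factors that drive genes of sterol and fatty acid synthesis. RNA levels of SCAP do not measure the stability of its protein. The vector libraries held 97718535, 76137965 and 78182851 reads, those of clone 1 held 50295812, 43173408 and 44945917, and those of clone 8 held 43136640, 44597981 and 38648268. FPKM values give no depth.

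PKM (ENSG00000067225.17, chromosome 15, 72199029 to 72231819, hg38) was checked first in each library. In MCF7 the parental libraries had 1107, 1156 and 1073 FPKM and the knockout libraries 259, 217 and 227 FPKM. In MDA-MB-231 the parental libraries had 1481, 1415 and 1397 FPKM and the knockout libraries 389, 390 and 368 FPKM. PKM fell by 2.25 on the log2 scale in MCF7 (SE 0.07, adjusted p = 1.37e-08) and by 1.90 in MDA-MB-231 (SE 0.07, adjusted p = 3.19e-08). Gene-level values do not separate the PKM1 and PKM2 forms. In the clone design PKM had 222799, 221909 and 221105 normalized counts with the vector, 119523, 121043 and 117733 in clone 1 and 198037, 188346 and 219871 in clone 8. Clone 1 was lower by a log2 difference of -0.89 (SE 0.01, adjusted p = 1.41e-12). Clone 8 differed by -0.14 (SE 0.06, adjusted p = 0.0529), which passed the threshold when the clone 8 library of replicate 3 was left out (-0.20, adjusted p = 0.000109) and in other settings (adjusted p = 0.0435 with a minimum of 50 counts, 0.0123 after median-centring, 0.0443 with robust variance, 0.0235 with all 9 libraries in 1 fit). Under quantile normalization it turned to 0.08 and was called higher (adjusted p = 0.0196).

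TMEM33 (ENSG00000109133.12, chromosome 4, 41935129 to 41960803, hg38) had 2707, 2768 and 2931 normalized counts with the vector, 10986, 10467 and 10925 in clone 1 and 7483, 8030 and 6832 in clone 8. The log2 differences were 1.95 in clone 1 (SE 0.03, adjusted p = 1.2e-12) and 1.41 in clone 8 (SE 0.06, adjusted p = 6.59e-07). TMEM33 was also higher in the knockouts of both lines. In MDA-MB-231 it rose from 26.3, 24.5 and 27.0 FPKM in parental libraries to 66.1, 60.8 and 69.1 FPKM in knockout libraries, a log2 difference of 1.32 (SE 0.09, adjusted p = 3.55e-06). In MCF7 it rose from 23.5, 22.2 and 23.9 FPKM to 34.7, 27.8 and 28.01 FPKM, a log2 difference of 0.37 (SE 0.09, adjusted p = 0.0104). The exact two-sided permutation p for PKM and for TMEM33 was 0.1 in each of these comparisons, the smallest that 3 libraries against 3 can give.

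**Figure D1:**
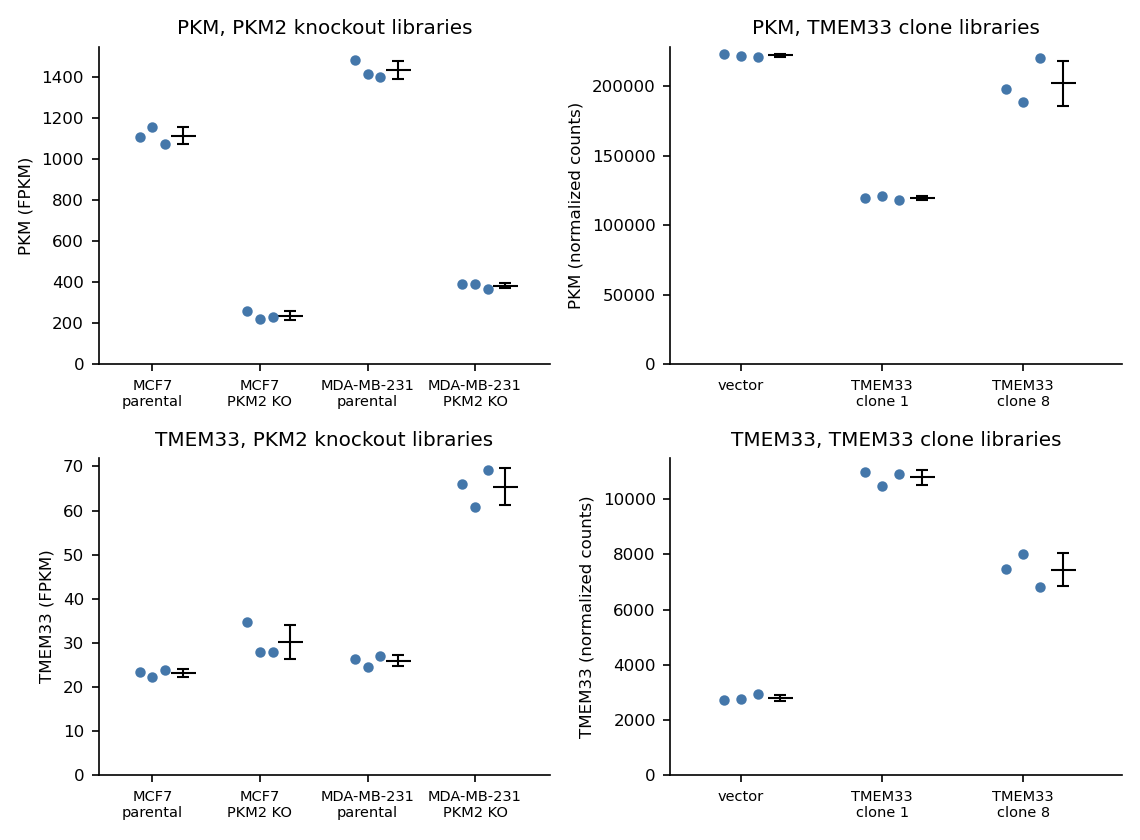
PKM and TMEM33 in each library, in FPKM for the knockout design and in normalized counts for the clone design. Points are libraries, bars the mean and whiskers the SD of 3; the libraries of knockout and parental cells, and of each clone and vector, do not overlap for either gene.

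Most genes of the short arm of chromosome 4 (4p), where TMEM33 lies, were higher with it in the MDA-MB-231 knockout and in the clones. In MDA-MB-231 knockout cells the 127 other tested protein-coding genes of 4p were all above 0, 123 of them called higher, with a median log2 difference of 1.10 and quartiles of 0.92 and 1.35. The 280 genes of the long arm (4q) had a median of -0.08. TMEM33 lay above 71.7% of the other 4p genes. SLC30A9, the neighbour of TMEM33, was higher by 1.01 (SE 0.08), GUF1 by 2.46 (SE 0.20) and OCIAD2 by 2.49 (SE 0.08). Of the protein-coding genes raised 2-fold or more in this comparison, 37.1% lie on 4p, against 3.81% in clone 1 and 6.12% in clone 8. In the clones the medians of the other 4p genes were 0.91 in clone 1 (150 genes, 82% above 0) and 0.98 in clone 8 (152 genes, 92.1% above 0), against 0.49 and 0.32 on 4q, and SLC30A9 was higher by 1.85 and 1.60. TMEM33 lay above 83.3% and 68.4% of the other 4p genes there. The 10 tested 4p genes nearest the centromere had medians of 1.84 in the knockout, 3.75 in clone 1 and 3.54 in clone 8, above the upper quartiles of the other 4p genes (1.35, 1.44 and 1.62). PHOX2B, a 4p gene near TMEM33, was lower in both clones (-0.70 and -0.76). In MCF7 the 4p median was 0.10 over 130 genes and the 4q median 0.02, and SLC30A9 was not called at 0.15 (adjusted p = 0.209). The level of the transgene cannot be told apart from that of the resident gene in these counts.

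**Figure D2:**
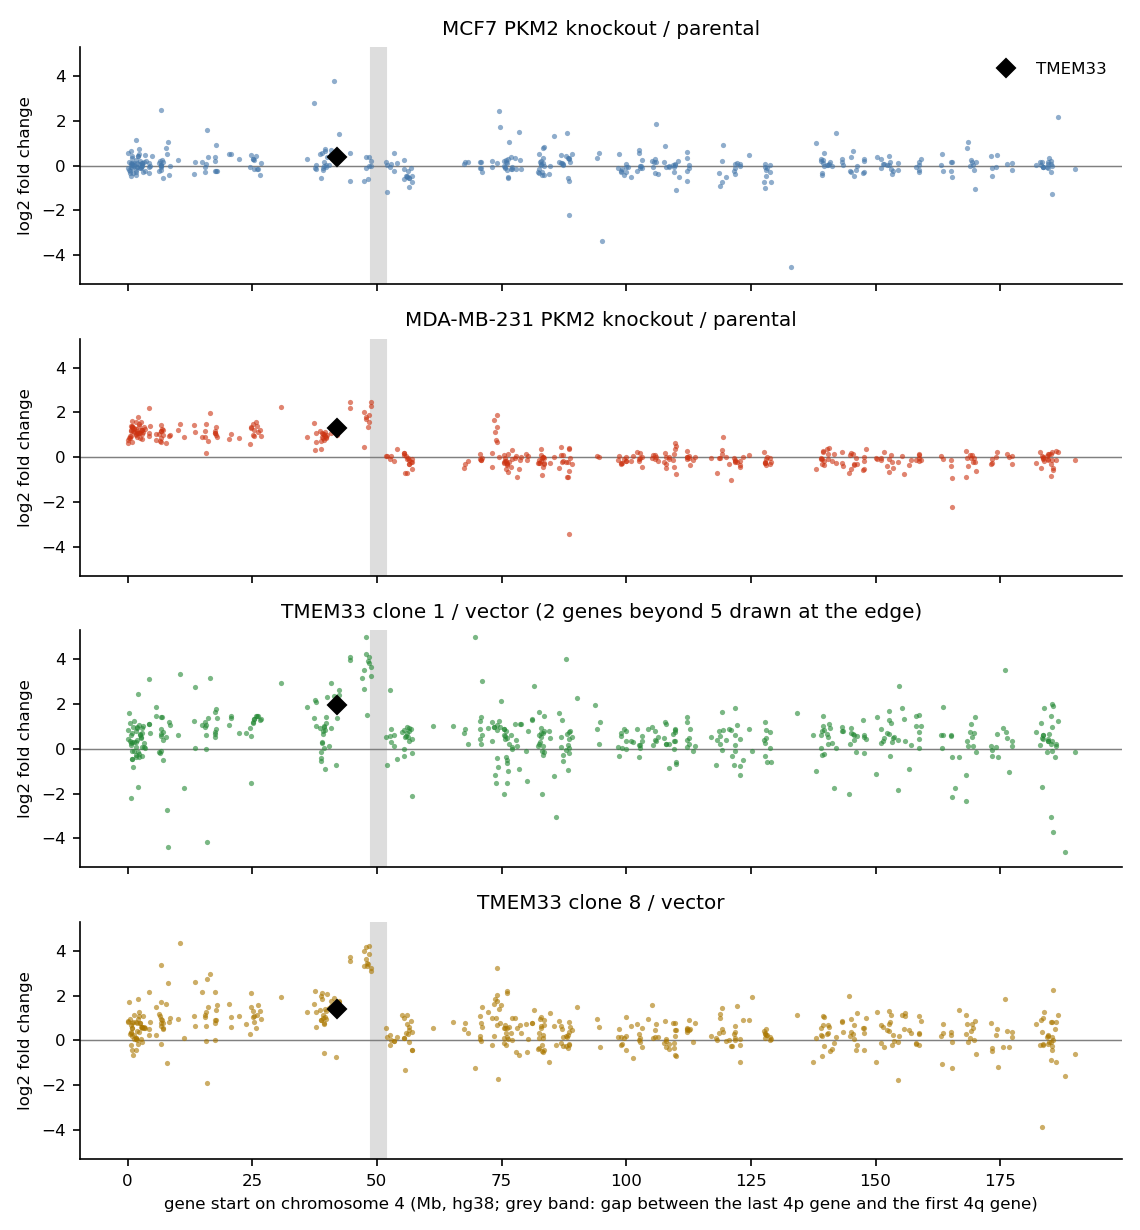
Log2 differences of protein-coding genes along chromosome 4 (position in Mb, hg38) in 4 comparisons, with TMEM33 as a black diamond and the gap between the arms in grey; in clone 1 the 2 genes beyond 5 are drawn at the edge. Of the other 4p genes, 100% lie above 0 in MDA-MB-231 knockout cells, 82% in clone 1, 92.1% in clone 8 and 59.2% in MCF7.

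The comparison of MCF7 knockout with parental cells asks what loss of PKM2 changes in a luminal line. Most cholesterol synthesis genes were lower, while fatty acid synthesis genes went both ways. Stearoyl-CoA desaturase (SCD) fell from 285 ± 2.47 FPKM (SD, n = 3) to 121 ± 9.58 FPKM, a log2 difference of -1.24 (SE 0.08, adjusted p = 1.14e-06). The squalene synthase gene FDFT1 differed by -1.79 (SE 0.09), fatty acid synthase (FASN) by -0.77 (SE 0.11) and SREBF1, which encodes SREBP1, by -0.75 (SE 0.14). LDLR, the lipoprotein receptor, was lower by -0.61 (SE 0.13), and INSIG1, which holds SCAP in the endoplasmic reticulum, by -0.42 (SE 0.10). HMGCR, HMGCS1 and SQLE, enzymes of cholesterol synthesis, differed by -0.36, -0.40 and -0.42. SREBF2 (0.13, adjusted p = 0.265), ACACA (-0.26, adjusted p = 0.116) and RNF5 (-0.18, adjusted p = 0.0791) were not called. ACACA and RNF5 were called lower after median-centring (adjusted p = 0.0302 and 0.00929), which moved the median of all genes by -0.11. ACACA was also called after the GC and length correction (0.0343) and without knockout replicate 3 (0.0498), and RNF5 without parental replicate 1 (0.0447) or knockout replicate 1 (0.0161). SCAP was higher by 0.36 (SE 0.12, adjusted p = 0.0447), a call that ended after median-centring (adjusted p = 0.119), quantile normalization (0.0633) and the GC and length correction (0.055), without a low-value filter (0.0782) or an intensity trend (0.0605), with the replicate number as a block (0.0847), with a fit of this line alone (0.121) and without parental replicate 1 (0.151), parental replicate 3 (0.104), knockout replicate 1 (0.157) or knockout replicate 2 (0.113).

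Among cholesterol synthesis enzymes in MCF7, 14 of 20 tested genes were lower and 0 higher (17 and 1 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 2.04e-07). Of 22 glycolysis genes 18 were lower and 1 higher (18 and 2 adjusted over the list alone), among them the aldolase ALDOC at -2.78 and PFKFB4 at -1.69 (median -0.69, adjusted p = 1.72e-13). Of 24 hypoxia and HIF1 targets 17 were lower and 3 higher (18 and 3 adjusted over the list alone), with CA9 at -3.11, NDRG1 at -2.55 and BNIP3 at -2.22 (adjusted p = 1.06e-10). NF-kB and inflammatory genes moved up, 8 of 12 higher and 0 lower (8 and 0 adjusted over the list alone), with TNFAIP3 at 1.12 and RELB at 1.09 (adjusted p = 0.000511). So did mesenchymal markers, 9 of 14 higher and 0 lower (10 and 0 adjusted over the list alone), with fibronectin (FN1) at 2.14 and TGFBI at 1.96 (adjusted p = 2.17e-06). These 5 lists kept their call with an estimated correlation (adjusted p = 0.0391, 0.0012, 0.0355, 0.0355 and 0.0355). YAP and cytoskeleton genes had 15 of 18 higher and 0 lower (15 and 0 adjusted over the list alone), with CYR61 at 1.84 and ANKRD1 at 1.80 (adjusted p = 2.04e-07, and 0.111 with an estimated correlation). Respiratory chain and citrate cycle genes had 14 of 41 lower and 3 higher (16 and 3 adjusted over the list alone), with COX6C at -1.41 (adjusted p = 1.49e-05, and 0.215 with an estimated correlation). G2 and M phase genes had 13 of 30 lower and 0 higher (13 and 0 adjusted over the list alone), with AURKA at -0.51 (adjusted p = 2.07e-05, and 0.35 with an estimated correlation).

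Interferon genes in MCF7 had 12 of 23 higher and 3 lower (15 and 4 adjusted over the list alone), with IFITM1 at 2.54 and IRF9 at 1.85 (adjusted p = 0.0124, 0.215 with an estimated correlation and 0.0529 without knockout replicate 3). ATF4 targets had 10 of 21 higher and 1 lower (11 and 3 adjusted over the list alone), with NUPR1 at 4.11 and PHGDH at 1.00 (adjusted p = 0.0274, 0.256 with an estimated correlation, 0.066 with a minimum of 5 FPKM and 0.0529 without knockout replicate 3). Stromal matrix genes had 4 of 5 higher and 0 lower (4 and 0 adjusted over the list alone), with COL5A1 at 2.95 (adjusted p = 0.0274, 0.262 with an estimated correlation, 0.123 without a low-value filter and 0.0529 without knockout replicate 3). Fatty acid synthesis genes had 4 of 19 lower and 3 higher (7 and 3 adjusted over the list alone), with ELOVL6 at -1.07 and AGPAT2 at 1.00 (adjusted p = 0.0458, 0.294 with an estimated correlation). That call ended with a minimum of 5 FPKM (0.125) and without parental replicate 2 (0.105), knockout replicate 1 (0.0544) or knockout replicate 3 (0.0679). MYC and ribosome biogenesis genes had 5 of 26 lower and 1 higher (5 and 1 adjusted over the list alone), with ODC1 at -0.99 (adjusted p = 0.0458, 0.494 with an estimated correlation). It ended with a minimum of 5 FPKM (0.0838), under quantile normalization (0.302) and without parental replicate 2 (0.0884), knockout replicate 1 (0.124) or knockout replicate 3 (0.0521). Ribosomal protein genes had a median of -0.09 (3 of 42 lower and 0 higher, 1 and 0 adjusted over the list alone, adjusted p = 0.0124, and 0.686 with an estimated correlation), which turned to 0.05 under quantile normalization and was not called without knockout replicate 1 (0.258). LXR targets (6 of 9 higher and 0 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.0547) and unfolded protein response genes (6 of 27 lower and 1 higher, 7 and 1 over the list alone, adjusted p = 0.0547) did not pass. They passed after median-centring (0.038 and 0.0204), with a pseudocount of 0.1 (0.0427 and 0.0499), without a low-value filter (0.00894 and 0.015) and without knockout replicate 1 (0.0464 and 0.0493). The LXR targets also passed with a minimum of 5 FPKM (0.00583) and without knockout replicate 2 (0.0473), and the unfolded protein response after the GC and length correction (0.0451) and with a variance trend in camera (0.0389). Not past either was the list of SREBP regulators and sterol uptake genes (adjusted p = 0.907), whose median was 0.11 and mean -0.01. The 12 other tested lists did not pass. Alternatives gave a call for NRF2 targets (0.0384), luminal markers (0.0439) and immediate early genes (0.0471) under quantile normalization, and for replication histones without knockout replicate 1 (0.013). Among the NRF2 targets, 10 of 27 were higher and 5 lower (12 and 7 adjusted over the list alone, adjusted p = 0.356), and in the S phase list the median was -0.02 and the mean 0.01 (adjusted p = 0.534).

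The largest rises in MCF7 were those of the acyltransferase gene GLYATL2 (4.55), UGT1A6 (4.47), NUPR1 (4.11), ITGB6 (3.80), EYA2 (3.79), LIMCH1 (3.78), BCAS1 (3.47) and LMO4 (3.36). NUPR1 went from 7.52 ± 0.357 to 138 ± 4.72 FPKM (SD, n = 3). LIMCH1 lies on 4p. UGT1A6 shares exons with the other UGT1A genes. The largest falls were those of the carbonic anhydrase CA4 (-5.01), CSTA (-4.65), PCDH10 (-4.51), SIGMAR1 (-4.26), PCGEM1 (-4.09), OLFM3 (-3.77) and SLC39A4 (-3.74). The short fragment annotation H19_1 (-4.27, SE 1.39, adjusted p = 0.0407) varied widely between libraries, and its call ended under 5 other settings and without parental replicate 1 (adjusted p = 0.123), parental replicate 2 (0.086), parental replicate 3 (0.0527), knockout replicate 2 (0.111) or knockout replicate 3 (0.0712). SIGMAR1 fell from 12.8 ± 0.387 to 0.2 ± 0.113 FPKM (SD, n = 3). In all, 2360 of 14365 genes were called higher and 1696 lower, 443 and 234 of them by 2-fold or more, and 42.6% of tested genes had no overlap between the groups, where chance gives 10%. After median-centring 1573 were higher and 2599 lower. Of 558 tested genes of the authors' deposited table for this comparison, 553 were called in the same direction and 0 in the opposite one.

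The comparison of MDA-MB-231 knockout with parental cells asks the same of a mesenchymal-like line. Most cholesterol synthesis genes were lower here as well. PCSK9, which directs the LDL receptor to degradation, fell from 17.2 ± 0.536 to 0.837 ± 0.255 FPKM (SD, n = 3), a log2 difference of -3.74 (SE 0.16, adjusted p = 1.56e-07). SCD differed by -1.61 (SE 0.08), INSIG1 by -1.41 (SE 0.10), FASN by -1.34 (SE 0.11), HMGCR by -1.31 (SE 0.07) and LDLR by -1.08 (SE 0.13). HMGCS1, SREBF2, SQLE and ACACA differed by -0.72, -0.67, -0.62 and -0.59. SREBF1 was lower by -0.53 (SE 0.14, adjusted p = 0.0222), a call that ended without parental replicate 1 (adjusted p = 0.0844) or knockout replicate 1 (0.0773). SCAP (-0.15, adjusted p = 0.395) and RNF5 (0.11, adjusted p = 0.286) were not called.

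Cholesterol synthesis enzymes in MDA-MB-231 had 15 of 20 lower and 2 higher (16 and 2 adjusted over the list alone), with EBP at -1.84, DHCR24 at -1.13 and IDI1 at -0.97 (median -0.65, adjusted p = 7.96e-09, and 0.0497 with an estimated correlation). NF-kB and inflammatory genes had 13 of 29 higher and 2 lower (16 and 2 adjusted over the list alone), with ICAM1 at 2.40, SAA1 at 2.05 and CXCL2 at 1.88 (adjusted p = 1.95e-05, and 0.0497 with an estimated correlation). Interferon genes had 12 of 26 lower and 1 higher (13 and 2 adjusted over the list alone), with IFIT1 at -2.22, IFIT2 at -2.03 and IFIT3 at -1.87 (adjusted p = 7.44e-08, and 0.0739 with an estimated correlation). G2 and M phase genes had 15 of 30 lower and 0 higher (19 and 0 adjusted over the list alone), with NDC80 at -0.72 and KIF20A at -0.66 (adjusted p = 5.09e-08, and 0.356 with an estimated correlation). Fatty acid synthesis genes had 8 of 18 lower and 0 higher (10 and 0 adjusted over the list alone), with FADS2 at -1.04 and ELOVL6 at -0.74 (adjusted p = 6.21e-06, and 0.0721 with an estimated correlation). SREBP regulators and sterol uptake genes had 7 of 19 lower and 0 higher (7 and 0 adjusted over the list alone), with TMEM97 at -1.11 (adjusted p = 0.00334, and 0.3 with an estimated correlation). S phase genes had 10 of 30 lower and 3 higher (12 and 3 adjusted over the list alone), with TYMS at -0.74 (adjusted p = 0.0107, and 0.551 with an estimated correlation). MYC and ribosome biogenesis genes had 9 of 26 lower and 3 higher (13 and 4 adjusted over the list alone), with NME1 at -0.65 and LYAR, a 4p gene, at 2.18 (adjusted p = 0.00972, and 0.551 with an estimated correlation).

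Lysosome genes in MDA-MB-231 had 12 of 25 higher and 2 lower (13 and 2 adjusted over the list alone), with LAMP2 at 0.69, GLA at 0.66 and the proton pump gene ATP6V1A at -0.87 (adjusted p = 0.0164, and 0.664 with an estimated correlation). LAMP2 and GLA lie on Xq, whose genes had a median of 0.66 in this comparison. Glycolysis genes had 6 of 22 lower and 3 higher (8 and 4 adjusted over the list alone), with ALDOC at -1.67 and ENO2 at 0.47 (adjusted p = 0.0216, 0.175 with an estimated correlation and 0.206 under quantile normalization). Hypoxia and HIF1 targets had 6 of 25 lower and 2 higher (8 and 2 adjusted over the list alone), with ADM at -0.78 (adjusted p = 0.048, and 0.611 with an estimated correlation). That call ended under quantile normalization (0.115), with a pseudocount of 0.1 (0.0525), a minimum of 5 FPKM (0.116), the replicate number as a block (0.0862), a fit of this line alone (0.0659) or the GC and length correction (0.076), and without parental replicate 2 (0.0599), parental replicate 3 (0.0835), knockout replicate 2 (0.111) or knockout replicate 3 (0.102). The 18 other tested lists did not pass. Alternatives gave a call for YAP and cytoskeleton genes (0.044), NRF2 targets (0.0433) and ribosomal protein genes (0.0371) after the GC and length correction. Without a low-value filter YAP and cytoskeleton (0.00932), stromal matrix (0.0413) and ribosomal protein genes (0.0464) passed. Ribosomal protein genes also passed without parental replicate 3 (0.0142) or knockout replicate 2 (0.00192), and NRF2 targets without knockout replicate 2 (0.0234). Mesenchymal markers had 3 of 23 higher and 2 lower (3 and 6 adjusted over the list alone, adjusted p = 0.517), with FN1 at -1.74 and TGFBI at 1.07, and YAP and cytoskeleton genes had 4 of 21 lower and 3 higher (8 and 3 over the list alone, adjusted p = 0.0786), with THBS1 at -1.83. Among oestrogen targets the median was -0.04 and the mean 0.14 (adjusted p = 0.749).

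The largest rises in MDA-MB-231 included the protease inhibitor PI3 (2.58), ICAM1 (2.40), KCTD4 (2.26), BCL2A1 (2.22) and the 4p genes OCIAD2 (2.49), GUF1 (2.46) and OCIAD1 (2.30). The short fragment annotation NEAT1_1 (2.58, SE 0.80, adjusted p = 0.0439) lost its call under 5 other settings and without parental replicate 1 (0.087), parental replicate 2 (0.11), knockout replicate 1 (0.136), knockout replicate 2 (0.0695) or knockout replicate 3 (0.0734). The largest falls were those of the MHC class II chaperone CD74 (-3.91), EMC10 (-3.81), PCSK9 (-3.74), PAEP (-3.44), SERPINB2 (-3.31), HLA-DRA (-3.31), L1CAM (-2.80) and STXBP6 (-2.40). CD74 went from 51.1 ± 2.36 to 2.97 ± 0.519 FPKM (SD, n = 3). HLA genes share sequence with one another, which leaves the value of HLA-DRA uncertain. In all, 1637 of 13923 genes were called higher and 1160 lower, 323 and 148 of them by 2-fold or more, and 38.8% had no overlap between the groups, where chance gives 10%. The count of lower genes was 753 without parental replicate 1 and 752 without parental replicate 2. Of 377 tested genes of the authors' deposited table, 365 were called in the same direction and 0 in the opposite one.

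Whether the knockout acts differently in the lines was tested as MDA-MB-231 minus MCF7. HMGCR (-0.94, SE 0.09, adjusted p = 6.31e-05), INSIG1 (-0.99, SE 0.14) and SREBF2 (-0.80, SE 0.12) had a more negative change in MDA-MB-231, and TMEM33 a more positive one (0.95, SE 0.13). HMGCS1 (-0.31, adjusted p = 0.0194), FASN (-0.56, adjusted p = 0.0299), SCD (-0.37, adjusted p = 0.0303) and PKM (0.34, adjusted p = 0.0222) passed narrowly. HMGCS1 no longer passed after median-centring (0.0734), nor FASN, SCD and PKM without a filter on low values (0.065, 0.0588 and 0.0511) or with the replicate number as a block (0.0819, 0.0759 and 0.0525). SCD and PKM no longer passed without an intensity trend (0.0585 and 0.0535), nor PKM under quantile normalization (0.063). Leaving out 1 library also ended these. FASN no longer passed without MCF7 parental replicates 1 (0.0509) or 3 (0.0565), MCF7 knockout replicates 1 (0.0639) or 2 (0.0503), MDA-MB-231 parental replicate 1 (0.0717) or MDA-MB-231 knockout replicates 1 (0.0553), 2 (0.0569) or 3 (0.0532). For SCD it was MCF7 parental replicates 1 (0.0553), 2 (0.0531) or 3 (0.0553), MCF7 knockout replicates 1 (0.0632) or 3 (0.0534) and MDA-MB-231 parental replicates 2 (0.0689) or 3 (0.0623). For PKM it was MCF7 knockout replicates 2 (0.0519) or 3 (0.0513), MDA-MB-231 parental replicates 2 (0.0516) or 3 (0.0513) and MDA-MB-231 knockout replicate 1 (0.0524). The differences of SCAP (-0.51, adjusted p = 0.052), LDLR (-0.47, 0.0938), SREBF1 (0.22, 0.473), SQLE (-0.20, 0.186), ACACA (-0.34, 0.165) and RNF5 (0.29, 0.0584) were not called. SCAP was called with a pseudocount of 1 (0.0499), a minimum of 5 FPKM (0.0433) and the GC and length correction (0.0369), RNF5 with a minimum of 5 FPKM (0.0494) and after median-centring (0.0199), and LDLR with the block (0.03). SCAP was also called without MCF7 parental replicate 2 (0.017) or knockout replicate 3 (0.0173), and RNF5 without MCF7 parental replicate 1 (0.0338) or knockout replicate 1 (0.0128). LDLR was also called without MCF7 parental replicate 2 (0.0473), MCF7 knockout replicate 3 (0.0429) or MDA-MB-231 knockout replicate 1 (0.0439). Cholesterol synthesis as a list did not differ (8 of 20 lower and 3 higher, or 8 and 4 adjusted over the list alone, adjusted p = 0.335).

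Glycolysis genes differed between the lines, with 15 of 23 higher in MDA-MB-231 minus MCF7 and 1 lower (17 and 1 adjusted over the list alone, median 0.53, adjusted p = 1.72e-07, and 0.0144 with an estimated correlation). Interferon genes had 17 of 30 lower and 1 higher (22 and 1 adjusted over the list alone, median -0.93, adjusted p = 7.29e-09, and 0.097 with an estimated correlation). YAP and cytoskeleton genes had 14 of 21 lower and 0 higher (15 and 0 adjusted over the list alone, adjusted p = 1.74e-07, and 0.152 with an estimated correlation). Hypoxia targets (15 of 25 higher and 3 lower, 17 and 4 adjusted over the list alone, median 0.59) and mesenchymal markers (11 of 23 lower and 0 higher, the same over the list alone, median -0.70) differed at adjusted p = 6.36e-06 and 2.74e-05, each 0.202 with an estimated correlation. Respiratory chain genes (13 of 41 higher and 2 lower, the same over the list alone, median 0.16, adjusted p = 0.00153), SREBP regulators and uptake genes (7 of 19 lower and 0 higher, 9 and 1 over the list alone, median -0.32, adjusted p = 0.0281) and stromal matrix genes (3 of 7 lower and 0 higher, 4 and 0 over the list alone, median -0.73, adjusted p = 0.0424) each gave 0.396 with an estimated correlation. Under quantile normalization the respiratory chain (0.105) and stromal matrix (0.0501) calls ended, and after the GC and length correction the SREBP regulator (0.0515) and stromal matrix (0.0753) calls. The SREBP regulator call also ended with the replicate number as a block (0.0606), and the stromal matrix call with a pseudocount of 1 (0.0518). The SREBP regulator call ended without MCF7 knockout replicate 1 (0.0747) or MDA-MB-231 parental replicate 3 (0.0609). The stromal matrix call ended without MCF7 parental replicate 1 (0.0557), MCF7 knockout replicates 2 (0.0587) and 3 (0.0568), MDA-MB-231 parental replicates 1 (0.0562) and 3 (0.063) and MDA-MB-231 knockout replicate 2 (0.0648). The 22 other tested lists did not pass. Alternatives gave a call for NRF2 targets under quantile normalization (0.0187), without a low-value filter (0.0349) and without MDA-MB-231 knockout replicate 2 (0.0499). They did so for LXR targets (0.0115) and lipid storage genes (0.0207) without that filter, for LXR targets with a minimum of 5 FPKM (0.0258) and for fatty acid synthesis without MCF7 parental replicate 2 (0.0491).

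The genes with the widest differences between the lines were CA4 (4.94) and CSTA (4.55), lower in MCF7 knockout cells only, and the noncoding genes AL109927.1 (6.27), AC108933.1 (5.16) and AC005702.4 (4.58). At the other end were GLYATL2 (-4.78), FST (-4.70), UGT1A6 (-4.52), CD74 (-4.06) and AC245470.1 (-3.99). AC245470.1 was not detected in MDA-MB-231, so its difference is its change in MCF7. GLYATL2 and UGT1A6 changed by -0.23 and -0.05 in MDA-MB-231. FST, the activin antagonist follistatin, rose by 2.44 in MCF7 and fell by 2.26 in MDA-MB-231. In all 1676 of 16177 genes had a more positive and 1767 a more negative change in MDA-MB-231, or 2022 and 1406 after median-centring. Of these 16177 genes, 12111 were tested in both lines. The others had a mean under 1 FPKM in 1 line, where little change can be seen.

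Over the 12111 genes tested in both lines, 332 were higher and 209 lower in both, where independent lists would share 215 and 125, and 171 and 178 were called in opposite directions. Across genes, which are not independent replicates, the fold changes correlated with r = 0.11, and 21 of 100 regroupings of the libraries gave an |r| as large. The regroupings include the real one, and the others still hold at least part of the knockout effects. Their share thus cannot decide whether the effects are shared. HLA-DRB1 (-1.94 in MCF7 and -2.96 in MDA-MB-231), PKM, ALDOC and C4orf19 (2.80 and 1.51), a 4p gene, moved together, with the pseudogene RPL7P23 and the small gene HYPK. FN1 (2.14 and -1.74), FST, SPNS2 (-1.62 and 1.38), C16orf45 (2.10 and -0.99) and AFF3 (-0.98 and 0.98) moved apart.

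The comparison of TMEM33 clone 1 with the vector asks what a higher level of TMEM33 changes in MDA-MB-231. Most cholesterol synthesis genes were lower, a list call that was lost with an estimated correlation (adjusted p = 0.161). INSIG1 fell from 3569 ± 105 to 738 ± 42.9 normalized counts (SD, n = 3), a log2 difference of -2.27 (SE 0.04, adjusted p = 3.72e-12). PCSK9 differed by -2.79 (SE 0.03), SQLE by -1.29 (SE 0.03), HMGCS1 by -1.20 (SE 0.02) and HMGCR by -1.15 (SE 0.03). SCD (-1.05), LDLR (-0.99), FASN (-0.95), SREBF1 (-0.91), SREBF2 (-0.91) and RNF5 (-0.85), a ubiquitin ligase of the endoplasmic reticulum, were lower as well, and ACACA by -0.13 (SE 0.03). SCAP was lower by -0.10 (SE 0.02, adjusted p = 0.00411), which was not called under quantile normalization (adjusted p = 0.155) or with all 9 libraries in 1 fit (0.0607). It turned to 0.30 after a correction for GC content and gene length, which shifted the changes of single genes by a median of -0.10. Fold changes of 11737 protein-coding genes with a mean of at least 100 normalized counts followed GC content with a Spearman correlation of -0.52, and those of all genes tested with -0.39.

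Lysosome genes in clone 1 had 23 of 25 lower and 2 higher, with the proteases CTSD at -2.77 and CTSA at -1.88 and NEU1 at -1.78 (median -0.96, adjusted p = 5.06e-06, and 0.161 with an estimated correlation). In this comparison each count adjusted over the list alone equals the one given, and no list kept its call with an estimated correlation. Cholesterol synthesis enzymes had 18 of 20 lower and 2 higher, with MVD at -2.63, MSMO1 at -2.14, MVK at -1.92 and EBP at 2.18 (median -1.35, adjusted p = 3.09e-05, and 0.161 with an estimated correlation). Interferon genes had 21 of 32 lower and 9 higher, with OASL at -4.88, IFIT2 at -4.23 and IFIT1 at -4.10 (adjusted p = 0.0219, and 0.212 with an estimated correlation). NF-kB and inflammatory genes had 22 of 32 lower and 10 higher, with CCL2 at -7.79, SAA1 at -6.87 and IL6 at -5.52 (adjusted p = 0.0298, and 0.212 with an estimated correlation). Unfolded protein response genes had 21 of 27 lower and 4 higher, with DNAJB11 at -1.39, calreticulin (CALR) at -1.26 and EDEM1 at 0.96 (adjusted p = 0.00405, and 0.212 with an estimated correlation). NRF2 targets had 20 of 27 lower and 6 higher, with ABCC3 at -4.18 and AKR1C1 at -3.12 (adjusted p = 0.0177, 0.212 with an estimated correlation and 0.0572 under quantile normalization). MYC and ribosome biogenesis genes had 19 of 26 higher and 7 lower, with POLR1B at 1.71, ODC1 at 1.37 and the 4p gene LYAR at 3.12 (adjusted p = 0.0318, and 0.212 with an estimated correlation).

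Messenger RNAs of the mitochondrial genome in clone 1 had 11 of 13 lower and 2 higher, with MT-CO2 at -1.43 (adjusted p = 0.00306). The share of reads from all genes of the mitochondrial genome was 1.27 to 1.30% against 2.27 to 2.33% with the vector. Replication histone genes had 13 of 17 lower and 0 higher, with HIST1H2AC at -2.37 (adjusted p = 0.00306); their transcripts mostly lack a poly(A) tail and share sequence. Antigen presentation genes had 12 of 16 lower and 1 higher, with TAPBP at -1.98 (adjusted p = 0.00927), and glycolysis genes 18 of 23 lower and 5 higher, with the lactate carrier SLC16A3 at -1.44 and HK2 at 1.27 (adjusted p = 0.00521). SREBP regulators and uptake genes had 13 of 19 lower and 5 higher, with NPC2 at -1.91 (adjusted p = 0.0365). These 5 lists each gave an adjusted p of 0.298 with an estimated correlation. Luminal markers had 15 of 20 lower and 4 higher, with SPDEF at -5.20 (adjusted p = 0.0372, and 0.298 with an estimated correlation), a call that ended without vector replicate 2 (0.0544) and after the GC correction (0.427). Stromal matrix genes had 9 of 13 lower and 2 higher, with COL5A1 at -6.84 and COL6A1 at -3.46 (adjusted p = 0.0372, and 0.244 with an estimated correlation). Fatty acid synthesis genes had 14 of 20 lower and 5 higher, with ACSS2 at -2.50, FADS2 at -1.81 and ACACB at 2.04 (adjusted p = 0.0418, and 0.324 with an estimated correlation). That call ended under quantile normalization (0.0839), with a minimum of 50 counts (0.0705), all 9 libraries in 1 fit (0.0573) or the GC and length correction (0.0502), and without clone 1 replicate 1 (0.0546), 2 (0.0575) or 3 (0.0512). The 16 other tested lists did not pass. The GC and length correction gave a call for G2 and M phase genes (0.000453), immediate early genes (0.0277) and hypoxia targets (0.0334). YAP and cytoskeleton genes passed without a low-value filter (0.0282) and with a variance trend in camera (0.045). Among p53 targets the median was 0.28 and the mean -0.19 (12 of 23 higher and 9 lower, adjusted p = 0.397), with GDF15 at -4.46 and BTG2 at 3.86. The leukocyte markers, with a median of -0.57 and a test direction of up (adjusted p = 0.92), included HCLS1 at 5.74 and LAPTM5 at -3.88. Ribosomal protein genes did not pass at a median of -0.07 (adjusted p = 0.246), a direction that turned under quantile normalization.

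The largest rises in clone 1 were those of FOXR2, the membrane glycoprotein gene PDPN (9.12), SV2B, CADM1 (8.59), RFPL4A (8.57), GIMAP8, OPCML (8.57) and ADAMTS2. With 0 vector reads, SV2B was at least 652-fold and ADAMTS2 at least 560-fold higher. FOXR2 had 2 vector reads and was 2272-fold higher (95% interval 628 to 18770), and GIMAP8 had 1 and was 2048-fold higher (367 to 80971). CADM1 went from 7.04 ± 1.83 to 3043 ± 6.79 normalized counts (SD, n = 3). The largest falls were those of EMC10, the placental phosphatase ALPP (-9.28), LDOC1L, IGF2, the cystatin CST1 (-8.20) and the cancer-testis genes MAGEA2 (-8.09), MAGEA2B (-8.01) and MAGEA6 (-7.95). EMC10 had 2 reads in clone 1 and was 2620-fold lower (95% interval 725 to 21633), LDOC1L had 2 and was 723-fold lower (200 to 5972), and IGF2 had 1 and was 1034-fold lower (185 to 40879). MAGEA2 and MAGEA2B are near-identical copies, so their separate values are uncertain. In all, 7385 of 18176 genes were called higher and 7290 lower, 2405 and 2374 of them by 2-fold or more, and 82.4% had no overlap between the groups, where chance gives 10%. Of 13364 tested genes past 0.05 in the authors' deposited table, 13359 were called in the same direction and 0 in the opposite one.

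The comparison of TMEM33 clone 8 with the vector puts the same question to a second clone. FDFT1 fell from 22499.7 ± 76.6 to 5060 ± 88.1 normalized counts (SD, n = 3), a log2 difference of -2.15 (SE 0.03, adjusted p = 1.22e-08). MVK (-2.24), PCSK9 (-2.20), FASN (-1.18), HMGCR (-0.86), SQLE (-0.81), HMGCS1 (-0.66), INSIG1 (-0.60), RNF5 (-0.57), SREBF2 (-0.56) and SCAP (-0.56) were lower. LDLR was higher by 0.86 (SE 0.05, adjusted p = 1.58e-06). SCD was lower by -0.17 (SE 0.04, adjusted p = 0.00572), which turned to 0.0037 under quantile normalization (adjusted p = 0.951). SREBF1 (-0.08, adjusted p = 0.366) and ACACA (0.08, adjusted p = 0.196) were not called. Both were called without clone 8 replicate 3 (adjusted p = 0.0156 and 0.0057), and the GC correction turned them to 0.24 and -0.24. The Spearman correlation of fold change with GC content was -0.51 over 11690 protein-coding genes with a mean of at least 100 normalized counts and -0.38 over all genes tested.

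Cholesterol synthesis enzymes in clone 8 had 20 of 20 lower, the same adjusted over the list alone, with MVD at -1.88 and IDI1 at -1.63 (median -1.22, adjusted p = 5.93e-09, and 0.0744 with an estimated correlation). Ribosomal protein genes had 42 of 42 lower, with RPL8 at -1.40 (median -0.46, adjusted p = 5.93e-09, and 0.534 with an estimated correlation). NF-kB and inflammatory genes had 22 of 32 higher and 6 lower, with TRAF1 at 2.46, CXCL10 at 2.19 and CCL2 at -5.41 (median 0.90, adjusted p = 9.88e-05, and 0.114 with an estimated correlation). Respiratory chain genes had 34 of 41 lower and 2 higher (34 and 3 adjusted over the list alone), with CYC1 at -1.53 (adjusted p = 3.91e-06, and 0.114 with an estimated correlation). Mesenchymal markers had 18 of 26 higher and 5 lower, with TGFBR2 at 1.69 and FN1 at 1.46 (adjusted p = 0.00347, and 0.173 with an estimated correlation). Hypoxia targets had 18 of 25 higher and 6 lower, with CA9 at 3.26, VEGFA at 1.65 and ADM at -1.53 (adjusted p = 0.0026, and 0.139 with an estimated correlation). Unfolded protein response genes had 18 of 27 higher and 7 lower, with ERN1 at 1.91 and SEL1L at 1.58 (adjusted p = 0.0177, and 0.173 with an estimated correlation). Replication histones had 12 of 16 lower and 1 higher, with HIST1H2AC at -1.63 (adjusted p = 0.00109, and 0.433 with an estimated correlation). Apart from the respiratory chain, the counts over these lists alone were equal. The 23 other tested lists did not pass, but 8 of them did after the GC and length correction: fatty acid synthesis (0.00612), ATF4 targets (0.0106), G2 and M phase (0.0176), fatty acid oxidation, MYC and ribosome biogenesis, NRF2 and oestrogen targets (0.024 each) and interferon genes (0.0314). Without a low-value filter fatty acid synthesis (0.0239), ATF4 and NRF2 targets (0.0312 each) and the mitochondrial genome's messenger RNAs (0.0369) passed. The NRF2 targets also passed with all 9 libraries in 1 fit (0.039) and with a variance trend in camera (0.0416), and the mitochondrial messenger RNAs with that trend (0.0499) and without clone 8 replicate 3 (0.0495). As reported, fatty acid synthesis had 13 of 20 lower and 3 higher (adjusted p = 0.0719), lysosome genes 14 of 25 lower and 8 higher (adjusted p = 0.437), both the same over the list alone, and LXR targets, with ABCA1 at 4.85, a median of -0.43 and a mean of 0.26 (adjusted p = 0.859). Glycolysis genes had a median of -0.16 and a mean of 0.04 (adjusted p = 0.426), with PGK1 at 1.45.

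The largest rise in clone 8 was that of the ferroxidase gene HEPH (6.86), from 271 ± 11.3 to 31681 ± 492 normalized counts (SD, n = 3), followed by NXF3 (6.38), ZDHHC15 (5.61), EPHB6 (5.05), SH2D2A (4.92), the sterol exporter ABCA1 (4.85), CX3CL1 (4.59) and TESPA1 (4.52). HEPH, NXF3 and ZDHHC15 lie on Xq, whose genes had a median of 0.98 in clone 8. The largest falls were those of PAEP, CARD11, SHANK2 (-7.34), the telomerase gene TERT, NKX2-5, B4GALNT4 (-6.48), SSX1 (-6.45) and NUP210. NKX2-5 had 0 reads in clone 8 and was at least 108-fold lower. PAEP had 1 read and was 689-fold lower (95% interval 123 to 27243), CARD11 had 3 and was 305-fold lower (104 to 1482), TERT had 2 and was 299-fold lower (82.5 to 2470), and NUP210 had 3 and was 112-fold lower (38.3 to 547). In all, 6228 of 17983 genes were called higher and 6301 lower, 1698 and 1207 of them by 2-fold or more, and 74.9% had no overlap between the groups, where chance gives 10%. Of 12115 tested genes past 0.05 in the authors' deposited table, 11867 were called in the same direction and 0 in the opposite one.

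**Figure D3:**
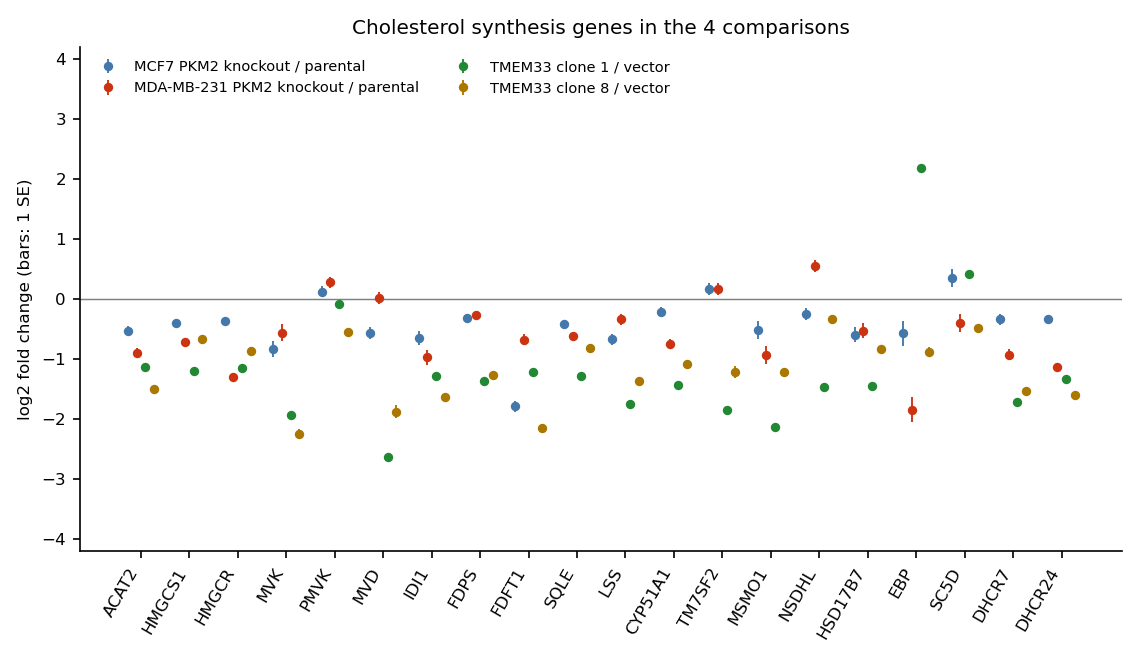
Log2 differences of the 20 cholesterol synthesis genes in the 4 comparisons, with bars of 1 SE. The list medians are -0.41 in MCF7, -0.65 in MDA-MB-231, -1.35 in clone 1 and -1.22 in clone 8, and EBP is the member with the widest spread, at -1.84 in MDA-MB-231 knockout cells and 2.18 in clone 1.

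The clones were compared with each other as clone 8 minus clone 1. LDLR (1.85, SE 0.04), INSIG1 (1.67, SE 0.06), SCD (0.87), SREBF1 (0.83), PKM (0.76), HMGCS1 (0.54), SQLE (0.48), SREBF2 (0.35), HMGCR (0.29), RNF5 (0.28) and ACACA (0.21) were higher in clone 8, and TMEM33 (-0.54), SCAP (-0.46) and FASN (-0.23) were lower. Without a filter on low values RNF5 (adjusted p = 0.0551) and FASN (0.0751) were not called. COL5A1 (8.32), ZG16B (8.82), MAGEA6 (8.58), MAGEA2 (8.74) and MAGEA2B (8.79) were the genes most above clone 1. GRAMD1B (-10.32), NUP210 (-9.80), TNS1 (-9.45), MAGEA11 and CT45A5 were the ones most below. NUP210 was 1434-fold lower (95% interval 490 to 6954), and MAGEA11 and CT45A5, with 0 reads in clone 8, were at least 423-fold lower each; CT45A5 has near-identical copies. Inflammatory genes (27 of 32 higher and 4 lower, median 2.32), unfolded protein response genes (24 of 27 higher and 1 lower, median 0.76), hypoxia targets (20 of 25 higher and 2 lower, median 0.78) and mesenchymal markers (19 of 25 higher and 3 lower, 20 and 3 over the list alone, median 0.99) were higher in clone 8, and MYC and ribosome biogenesis genes lower (22 of 26 lower and 3 higher, median -0.67). These 5 lists kept their call with an estimated correlation, each with an adjusted p of 0.0438. Cholesterol synthesis genes as a list did not differ (11 of 20 higher and 8 lower, the same over the list alone, adjusted p = 0.725), with a median of 0.24 and a mean of -0.01. In all, 5658 of 17477 genes were higher and 5626 lower, 1961 and 1104 of them by 2-fold or more, and 70.2% had no overlap between the clones, where chance gives 10%.

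A further 14 lists differed between the clones at the preset correlation and lost that call with an estimated one. Lysosome genes had 20 of 25 higher in clone 8 and 1 lower (median 0.90, adjusted p = 1.12e-06, and 0.157 with an estimated correlation), ribosomal protein genes 34 of 42 lower and 1 higher (median -0.39, adjusted p = 1.12e-06, and 0.485), and respiratory chain genes 30 of 41 lower and 6 higher (median -0.30, adjusted p = 0.00146, and 0.115). The mitochondrial genome's messenger RNAs had 11 of 13 higher and 1 lower (median 0.46, adjusted p = 0.00146, and 0.305). Interferon genes had 21 of 31 higher and 8 lower (median 1.18, adjusted p = 0.00387, and 0.113 with an estimated correlation), and YAP and cytoskeleton genes 15 of 22 higher and 4 lower (median 0.50, adjusted p = 0.0019, and 0.157). SREBP regulators and uptake genes, among them LDLR, had 14 of 19 higher and 4 lower (median 0.49, adjusted p = 0.0044, and 0.115 with an estimated correlation). ATF4 targets (14 of 21 higher and 6 lower, median 0.49), antigen presentation genes (11 of 16 higher and 4 lower, median 0.84) and luminal markers (13 of 19 higher and 4 lower, median 0.83) each had an adjusted p of 0.0236, which became 0.274, 0.403 and 0.387 with an estimated correlation. Stromal matrix genes (8 of 13 higher and 2 lower, median 1.72) and glycolysis genes (14 of 23 higher and 4 lower, median 0.37) had 0.0252, which became 0.157 and 0.599. S phase genes had 18 of 30 lower and 6 higher (median -0.26, adjusted p = 0.037, and 0.157 with an estimated correlation). LXR targets had 7 of 11 higher and 1 lower (median 0.49, adjusted p = 0.0295, 0.228 with an estimated correlation and 0.0553 without clone 8 replicate 3). After the GC correction the calls of LXR targets (0.0847), glycolysis (0.0727) and antigen presentation (0.0725) ended, with a minimum of 50 counts those of S phase (0.0534) and luminal genes (0.086), and with the replicate number as a block that of LXR targets (0.0534). Adjusted over the list alone, 35 ribosomal protein genes were lower, 12 mitochondrial ones and 7 S phase and 7 respiratory chain genes higher, and 3 stromal matrix genes lower; the other counts were equal. Of the 12 lists not past the threshold, G2 and M phase genes passed after the GC correction (0.0487) and without clone 8 replicate 3 (0.0481), and serine and pentose phosphate genes (0.0209) and oestrogen targets (0.0341) without a low-value filter.

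The clones shared 3991 genes called higher and 4371 called lower among 17477 tested in both, where independent lists would share 2357 and 2619. Noncoding transcripts such as RP11-804A23.4 and RP11-21J18.1 head the shared rises. In opposite directions 1169 and 1252 genes were called, among them GPR65, KBTBD11, GRAMD1B, NUP210, MAGEA11 and CT45A5. Across genes the fold changes correlated with r = 0.49. Unchanged groups simulated against the same 3 vector libraries gave a mean r of 0.54 (0.50 to 0.59), since shared controls alone make fold changes correlate. The covariance was 0.519 against a simulated mean of 0.0361. The 3 vector libraries are too few to split by clone. Unchanged groups shared 0 called genes, but a vector difference was not simulated.

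Genes of the MDA-MB-231 knockout were set beside those of the clones to ask whether knockout and TMEM33 overexpression change the same genes. PCSK9 (-3.74 in the knockout and -2.79 in clone 1), EMC10, PAEP and L1CAM (-2.80 and -5.32) were lower in the knockout and in clone 1, with CTD-2033D15.2 and CTD-2545M3.2, while SERPINB2 (-3.31 and 3.90), SAA1 (2.05 and -6.87), ZG16B (1.98 and -6.77), LAPTM5 (1.89 and -3.88) and EBP (-1.84 and 2.18) went opposite ways. In knockout and clone 8, EMC10, PAEP and ADGRE1 (-2.59 and -5.05) were lower and the 4p genes OCIAD2 (2.49 and 3.08) and GUF1 (2.46 and 3.72) higher, while GPR65 (2.43 and -3.76), HEPH (-2.24 and 6.86), THBS1 (-1.83 and 2.08) and PRSS2 (-1.55 and 3.55) went opposite ways. The knockout shared 556 higher and 572 lower genes with clone 1, where independent lists would share 686 and 510, and 871 and 478 were opposite (r = 0.03 across genes, 70 of 100 regroupings as large). With clone 8 it shared 744 and 630, where independent lists would share 595 and 455, and 531 and 322 were opposite (r = 0.12, 36 of 100 regroupings as large). The knockouts' fold changes rose with GC content (Spearman 0.22 in MDA-MB-231, 0.13 in MCF7), opposite to the clones'. How much this and the rise of 4p in the knockout and both clones change these overlaps was not tested. The MCF7 knockout shared 792 higher and 775 lower genes with clone 1 (901 and 673 if independent, r = -0.03, 66 of 100 as large) and 810 and 823 with clone 8 (741 and 620 if independent, r = 0.05, 43 of 100 as large). All these regroupings still hold at least part of the real effects, so their shares cannot decide whether effects are shared. BMP5 (-3.52 in MCF7 knockout cells and -4.77 in clone 1) was lower in both, and COL5A1 (2.95 and -6.84) and ABCC3 (2.89 and -4.18) went opposite ways, as did CA9 (-3.11 and 3.26) in clone 8.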

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

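The tests of the 4p pattern were chosen only after the result was seen, and the GC and length correction was added after the clones' trend with GC content was seen, with its bounds for the GC and cholesterol patterns written before its results.

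The difference of the knockout effects, MDA-MB-231 minus MCF7, was itself tested and passed for 3443 of 16177 genes. Of the genes fixed before the data were examined, PKM (0.34) and TMEM33 (0.95) had a more positive change in MDA-MB-231, and SREBF2 (-0.80), INSIG1 (-0.99), HMGCR (-0.94), HMGCS1 (-0.31), FASN (-0.56) and SCD (-0.37) a more negative one. PKM fell less there (-1.90 against -2.25 in MCF7), and INSIG1, HMGCR, HMGCS1, FASN and SCD fell more. At the ends of the range stood AL109927.1 (6.27), AC108933.1 (5.16), CA4 (4.94), AC005702.4 (4.58) and CSTA (4.55), and GLYATL2 (-4.78), FST (-4.70), UGT1A6 (-4.52), CD74 (-4.06) and AC245470.1 (-3.99), which was not detected in MDA-MB-231. Among the gene lists, the tested difference had a median of -0.32 for SREBP regulators and sterol uptake, 0.53 for glycolysis, 0.16 for the respiratory chain, 0.59 for hypoxia targets, -0.93 for interferon genes, -0.70 for mesenchymal markers, -0.73 for the stromal matrix and -0.75 for YAP and cytoskeleton genes. With an estimated correlation only glycolysis kept its call (adjusted p = 0.0144), and the others gave 0.097 to 0.396. Of 100 splits of the libraries within the lines, 1, the real one, gave as many genes, and the highest other gave 1441. The splits ask whether the libraries group by chance and not whether the effects are equal, since some keep the real grouping of 1 line. They cannot exclude a chance difference between the knockout cells derived from each line.

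The difference between the clones, clone 8 minus clone 1, was also tested and passed for 11284 genes. Higher in clone 8 were PKM (0.76), SREBF1 (0.83), SREBF2 (0.35), INSIG1 (1.67), RNF5 (0.28), LDLR (1.85), HMGCR (0.29), HMGCS1 (0.54), SQLE (0.48), SCD (0.87) and ACACA (0.21), and lower TMEM33 (-0.54), SCAP (-0.46) and FASN (-0.23). Genes of 3p, where SCAP lies, had a median of -0.55. At the ends of the range stood ZG16B (8.82), MAGEA2B (8.79), MAGEA2 (8.74), MAGEA6 (8.58) and COL5A1 (8.32), and GRAMD1B (-10.32), NUP210 (-9.80), TNS1 (-9.45), MAGEA11 (-9.05) and CT45A5 (-9.03); where a clone had 0 to 3 reads these fitted values depend on the added count. The list medians were 0.49 for SREBP regulators and uptake, 0.49 for LXR targets, 0.37 for glycolysis, -0.30 for the respiratory chain, 0.76 for the unfolded protein response, 0.49 for ATF4 targets, 0.78 for hypoxia, -0.67 for MYC and ribosome biogenesis and -0.26 for S phase. They were 1.18 for interferon, 2.32 for inflammatory, 0.84 for antigen presentation, 0.83 for luminal, 0.99 for mesenchymal, 1.72 for stromal matrix, 0.50 for YAP and cytoskeleton, 0.90 for lysosome, -0.39 for ribosomal protein and 0.46 for mitochondrially encoded genes. With an estimated correlation the unfolded protein response, hypoxia, MYC and ribosome biogenesis, inflammatory and mesenchymal lists kept their call (adjusted p = 0.0438 each), and the 14 others lost it (0.113 to 0.599).

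For each comparison of 3 libraries with 3, 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The others mix the real groups, which widens their spread, so their low counts do not measure chance. The real and highest other counts were 4056 and 3 for MCF7, 2797 and 3 for the MDA-MB-231 knockout, 14675 and 0 for clone 1, 12529 and 0 for clone 8, and 11284 and 0 for clone 8 minus clone 1.

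The first pattern weighed is the rise of 4p genes with TMEM33 in MDA-MB-231 knockout cells and both clones. A change of TMEM33 alone in the knockout would leave the other 4p genes near 0, and their median was 1.10; the construct alone would do so in the clones, and after the GC and length correction the smaller of the 4p and 4q differences was 0.569. The same value, the smallest over the 3 comparisons, goes against GC content or gene length as the cause. The 10 genes nearest the centromere on each side differed by 1.78, 3.22 and 3.42 in the knockout, clone 1 and clone 8 (-0.05 in MCF7), as a copy number difference of the arm or a part of it would give, but those on 4p lay above the upper quartile of the other 4p genes by 0.490 or more, which goes against a uniform change of the whole arm. Both clones were set against the same vector libraries. Between the clones (clone 8 minus clone 1) the median of the other 4p genes was 0.02 and the step at the centromere -0.07. The 2 rises are thus not separate evidence, as a difference of the vector cells or of each clone could give both. DNA was not analysed here, and whether the knockout or TMEM33 acts on the arm, or whether the cells were derived from subclones that differed beforehand, stays open.

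The second pattern is the trend of both clones' fold changes with GC content. Thinning the 9 libraries to the shallowest depth left the weaker Spearman correlation at -0.512. Random thinning changes counting noise only, so it cannot exclude library differences that go with depth. For GC content or length as the whole cause of what the clones share, both bounds written beforehand were met: the corrected correlation of 0.412 lay under the simulated highest of 0.587 and above 0.6 of the uncorrected 0.488, so the order of the bounds was settled after the result was seen. The simulated bound cannot decide, since noise with shared controls alone gave a mean r of 0.539 with a covariance of 0.0361; the covariance, 0.519 before and 0.377 after the correction, lay above the simulated highest of 0.0399. Between the clones (clone 8 minus clone 1) the correlation with GC content was 0.13, so the trend could also lie in the shared vector libraries. Library preparation and a biological change of the clones could each give the trend, and were not separated.

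The third pattern is the fall of cholesterol synthesis genes in all 4 comparisons. After the GC and length correction the higher of the clone medians was -1.23, and under median-centring and quantile normalization the highest of the medians was -0.417, so neither explains the fall. The clones lost the list's call with an estimated correlation (0.161 and 0.0744). No biological explanation was tested. Culture density and serum, which also move these genes, are not given in the labels used here.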

How the results depend on the processing

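The GC and length correction was chosen only after the clones' trend with GC content was seen, and camera with a variance trend after the values without it; the other alternatives were set before. Over all alternatives, named genes were alike in 10220 cases, lost calls in 309, gained calls in 26 and changed direction in 6. Lists gave 3492, 181, 57 and 1, turns of uncalled lists aside. Of the counts of called genes, 214 stayed within 1.5 times and 4 did not. A count model for the knockout libraries was not run, for the reason given above. The cause of these dependences was not tested.

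Median-centring gave 1573 higher and 2599 lower genes in MCF7. Quantile normalization turned the direction of the ribosomal protein list in MCF7 (adjusted p = 0.196), PKM in clone 8 to 0.0778 (called higher, adjusted p = 0.0196) and SCD in clone 8 to 0.0037. PKM in clone 8 became called with a minimum of 50 normalized counts (-0.14), robust variance (-0.14), all 9 libraries in 1 fit (-0.14) and median-centring (-0.21). The GC and length correction turned SCAP in clone 1 to 0.30, RPS15 in clone 1 to 0.08, SREBF1 in clone 8 to 0.24 and ACACA in clone 8 to -0.24. With an estimated correlation the cholesterol list had an adjusted p of 0.161 in clone 1 and 0.0744 in clone 8, and with a variance trend as well 0.127 and 0.06.

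Among genes changed 2-fold or more, the knockouts shared 11 higher and 10 lower genes (3.93 and 0.963 if independent), the MDA-MB-231 knockout shared 87 and 56 with clone 1 (27.5 and 15.5) and 110 and 40 with clone 8 (22.1 and 6.71), and the clones shared 739 and 600 (165 and 162). For the MDA-MB-231 knockout and clone 1 the shared rises are thus above the number for independent lists here, and below it (556 against 686) among all called genes. Of the protein-coding genes raised 2-fold or more in this knockout, 37.1% lie on 4p, which also rose in both clones. Genes of Xq rose in the knockout and clone 8 (medians 0.66 and 0.98). How much these arms or the GC trends change the overlaps was not tested. The correlation between the MDA-MB-231 knockout and clone 1 turned to -0.0243 with a stricter minimum.

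The replicate numbers do not pair the libraries: correlations between equally numbered libraries ranged from -0.08 to 0.03, and 1 of 12 libraries matched its own number best. With the replicate number as a block, 1956 genes were higher and 1456 lower in MCF7, 1279 and 805 in the MDA-MB-231 knockout, 1352 and 1343 for their difference, 7376 and 7303 in clone 1, 5898 and 5959 in clone 8 and 5402 and 5308 between the clones.

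Leaving out 1 library at a time gave 1820 to 2218 higher and 1320 to 1510 lower genes in MCF7, 1170 to 1370 and 752 to 971 in the MDA-MB-231 knockout (753 lower without parental replicate 1, 752 without parental replicate 2), 1396 to 1628 and 1413 to 1728 for the difference, 7133 to 7275 and 6933 to 7286 in clone 1, 5683 to 6542 and 5578 to 6784 in clone 8, and 5130 to 5947 and 5007 to 6046 between the clones. PKM ranged from -2.32 to -2.19, -1.92 to -1.88, -0.90 to -0.88 and -0.20 to -0.0889 (MCF7, MDA-MB-231, clone 1, clone 8), and in clone 8 it was called only without clone 8 replicate 3 (-0.20, adjusted p = 0.000109). TMEM33 ranged from 0.27 to 0.42, 1.27 to 1.37, 1.92 to 1.98 and 1.35 to 1.47. The adjusted p of the cholesterol list ranged from 3.63e-08 to 1.38e-06, 1.04e-09 to 2.08e-07, 2.77e-05 to 6.54e-05 and 7.79e-09 to 4.31e-08.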

Other observations

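The chromosome arm medians in this part were examined only after the 4p result was seen.

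Other chromosome arms moved as blocks too. Genes of Xq had a median of 0.66 in MDA-MB-231 knockout cells (246 genes, 158 higher and 10 lower) and 0.98 in clone 8 (300 genes, 268 higher and 11 lower), against 0.08 in clone 1 and -0.01 in MCF7. In clone 1 the medians were -0.91 on 18p, -0.59 on 20q and 0.61 on 3p. DNA was not analysed here.

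Of the MAGEA and CT45A genes at the ends of clone 8 minus clone 1, some lay above clone 1 (MAGEA6 at 8.58, MAGEA2 at 8.74) and others below (MAGEA11 and CT45A5); no list of such genes was tested. MAGEA6 was at 34.7 ± 13.4 normalized counts in clone 1 against 8439 ± 205 with the vector (SD, n = 3). PDPN went from 2.12 ± 1.5 to 1577 ± 15.2 normalized counts in clone 1 (SD, n = 3).

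The most abundant gene of the clone 1 libraries was MMP1, with 2.35 to 2.36% of reads, and EEF1A1 in the vector and clone 8 libraries. Among the 9 libraries, clone 8 replicate 3 lay farthest from its group, with a chi-square per degree of freedom of 13.7 and 27.1 against the other replicates, where all pairs ranged from 3.35 to 27.1.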
